A study of Mus musculus with 6 samples.

How the data were processed

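Liver total RNA of 3 prenatal and 3 adult mice was hybridised to single-colour arrays labelled with Cy3, 1 array per sample. Per the labels, the labelling used oligo(dT) and random primers together. Groups and replicate numbers were taken from the sample titles and source names. The authors deposited scanner output, whose processed signals are spot intensity values on a linear scale after background subtraction, made with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. The authors also deposited a value table whose normalisation is not named in the sources used here. Set against the scanner values, the authors' table held log2 values that were not centred by probe: 96.8% of them lay within 0.01 of a quantile normalisation of the log2 processed signals, the column medians were 6.10, 6.02 and 6.11 for the prenatal and 5.94, 6.05 and 6.05 for the adult arrays, and all 17307 of its probes were well above background on at least 3 arrays. It was used as an alternative, and its membership to divide the tested probes into tabled and untabled ones.

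The main values were log2 of the processed signal minus the 75th percentile of each array over spots that are not controls. The raw 75th percentile was 73.7, 151.9 and 83.1 on the prenatal arrays and 114.3, 69.4 and 78.4 on the adult arrays. Spots with an outlier flag were left out and the spots of one probe averaged. Over the 15 messenger RNA probes printed on repeated spots, the median SD between the spots of a probe was 0.03 to 0.05 (log2) per array. For single probes, the median over arrays reached 0.389 for Ldhal6b and 0.385 for Gk. The other tested probes had no repeated spots, so this spread is not known for them. Probes were tested when the scanner flag put them well above background on at least 3 of the 6 arrays (for repeated probes, on at least as many spots as not), which left 32336 of 60915 probes. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), adjusted over all tested probes by the Benjamini-Hochberg method, with a threshold of 0.05. Positive log2 fold changes mean higher in adult liver. Gene lists and probe families were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Gene lists were also tested with fry.

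The 15 probes with a reference accession were named through a RefSeq gene table of assembly GRCm38.p6, in which all 15 matched a protein-coding gene. Probe names on the array refer to another build, so no coordinates are given. No probe could be classed as noncoding by an accession or gene type, so the planned count of noncoding probes and the comparison of noncoding genes with their nearest coding neighbours were not run. Lists were tested where at least 5 members were measured, which held for 1 list. The text names the genes by a rule fixed before the data were examined: the 5 coding and 5 noncoding genes with the largest called change in each direction whose groups do not overlap, up to 4 called members of each list in its majority direction and 2 in the other, and 22 genes whatever their values. The other genes with a named probe are shown because there are only 15. The split into tabled probes, the probe families and the probe IDs were chosen after the data were examined.

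The fit was tested on simulated values for the 32250 probes with a value on every array. With 200 changed probes, 68% of those changed by a log2 of 3 and 14% of those changed by a log2 of 2 were recovered, and 0% of those changed by 1. With 30% of probes changed, 96.6%, 87.7% and 33.9% were recovered at a log2 change of 3, 2 and 1, and 4.4% of the calls were false. Alternatives tried were the background correction, the scaling, the filter on dim probes, the variance model, the slide and the replicate number as blocks, array weights, the authors' table, and leaving out each array.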

Results

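Long noncoding RNA and other transcripts were measured in mouse liver before birth and in adulthood on single-colour arrays. The prenatal group held 3 arrays of liver RNA from embryonic day 18, for which another label gives a slightly later stage, and the adult group held 3 arrays of liver RNA from animals of 2 months. The series describes each group as RNA from 3 different animals, and the extraction label says that total RNA of the C57BL/6 strain was bought from a supplier. The source and title labels of the prenatal samples say liver, whereas their tissue field says embryo. Each array carried 62939 features. Between 45.1% and 60.5% of the 61500 spots that were not controls lay well above background on an array. No spot was saturated. The number of arrays limits the precision of every value below.

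The comparison asked which transcripts differ in level between prenatal and adult liver. The array files give a reference accession for 15 messenger RNA probes, each printed on 20 spots, and no gene name for the other 32321 tested probes. Of these 15 genes, Tfrc and Tuba1b were higher in prenatal liver and B2m was higher in adult liver. Tfrc encodes the transferrin receptor, which takes up iron and is abundant on erythroid precursors. Its normalised log2 signal was 8.14 ± 0.15 (SD, n = 3) in prenatal and 4.52 ± 0.23 (SD, n = 3) in adult liver, a 12.3-fold higher level before birth (limma adjusted p = 0.000182). Tuba1b, an alpha tubulin of the microtubule cytoskeleton, had a log2 signal of 10.27 ± 0.38 (SD, n = 3) in prenatal and 7.48 ± 0.21 (SD, n = 3) in adult liver, which is 6.93-fold higher before birth (limma adjusted p = 0.000908). B2m, the light chain of MHC class I molecules, had a log2 signal of 6.80 ± 0.32 (SD, n = 3) in prenatal and 9.55 ± 0.21 (SD, n = 3) in adult liver, a 6.74-fold higher level in the adult (limma adjusted p = 0.000785). The 3 prenatal and 3 adult values did not overlap for 9 of the 15 genes, these 3 and 6 that were not called. Chance alone gives this in a share of 0.1 of genes with 3 against 3 values. That share is no yardstick for the count of 9, because all genes were read on the same 6 arrays. The share over all tested probes was not counted, but 13076 of 32336 had an unadjusted limma p under 0.05. A gap could be narrow: for G6pd2 the lowest prenatal value was -1.48 and the highest adult value -1.51. Tfrc, Tuba1b and B2m were also the 3 genes called when p was adjusted over the list alone.

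**Figure D1:**
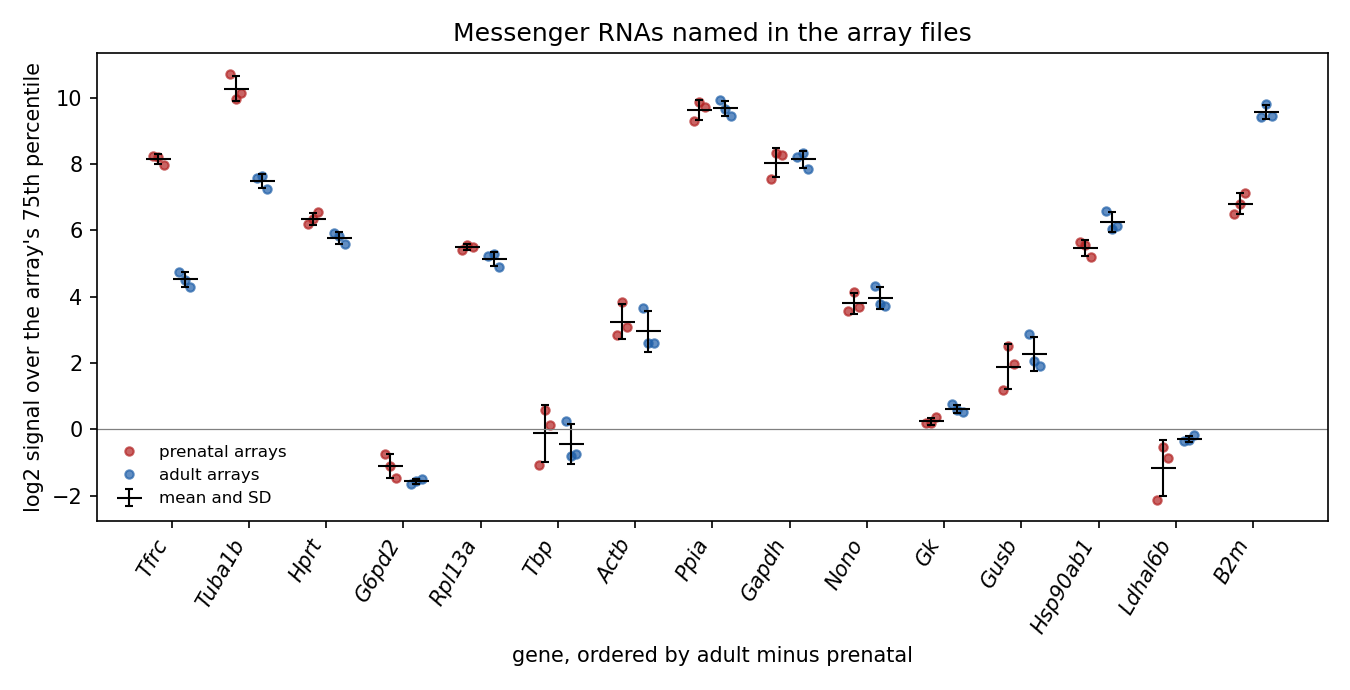
Normalised log2 signal of the 15 messenger RNAs with an accession in the array files, one point per array and bars for the mean and SD of 3 arrays. Tfrc and Tuba1b lie higher on all 3 prenatal arrays and B2m lies higher on all 3 adult arrays, whereas the other 12 genes did not pass the threshold.

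The other 12 genes did not pass the threshold. Hsp90ab1, a cytosolic heat shock protein, had a log2 difference, adult minus prenatal, of 0.78 with a standard error of 0.28 and an adjusted p of 0.0793 in the limma fit. For Hprt, a purine salvage enzyme, the difference was -0.57 with a standard error of 0.25 and a limma adjusted p of 0.131. The lactate dehydrogenase relative Ldhal6b had a difference of 0.89, with prenatal values that spread by an SD of 0.84, and a limma adjusted p of 0.177. Gapdh, a glycolytic enzyme, had a log2 signal of 8.04 ± 0.44 (SD, n = 3) before birth and 8.14 ± 0.26 (SD, n = 3) in the adult. Actb, the cytoplasmic actin, had 3.25 ± 0.52 (SD, n = 3) and 2.95 ± 0.62 (SD, n = 3). Gapdh and Actb belong to the genes named whatever their values, of which 20 of 22 had no named probe here.

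The gene lists fixed before the data were examined could be read only in part. Of 43 lists with 1082 distinct genes, 38 had no member with a named probe, and 5 had at least 1. The housekeeping list had 8 measured members, of which B2m was higher in adult liver, none was higher in prenatal liver, and 7 did not pass the threshold; adjusted over the list alone, 1 member was called. The mean log2 difference of the list was 0.22 and its median was -0.12, so they differ in sign, and limma's camera test against all other probes gave an adjusted p of 0.952 over the 1 list tested, or adjusted p = 0.98 with an estimated correlation (0.65). With limma's fry, the adjusted p was 0.538 for a shift in one direction and 2.63e-05 for change in either direction. In the limma fit, the unadjusted p was 3.02e-05 for B2m and 0.0544 or more for each of the other 7 members. The fry result for either direction therefore need not describe the whole list. The erythroid list had 1 measured member, Tfrc, which was higher in prenatal liver. B2m was the measured member of both the list of MHC class II and antigen presentation and the list of interferon-stimulated genes. Gapdh was the measured member of the list of glycolytic enzymes and did not pass the threshold.

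Across all tested probes, 8987 of 32336 differed between the groups at a limma adjusted p under 0.05. Of these, 5121 were higher in adult and 3866 were higher in prenatal liver. At least 2-fold change was seen for 8421 probes, 4784 higher in adult and 3637 higher in prenatal liver. The 2-fold count was 4549 with a normexp background correction that added an offset of 50, which shrinks the fold changes of dim probes. It was 5212 on probes well above background on all 6 arrays, and 5313 and 5387 without adult replicate 2 and adult replicate 3. With no limit on the fold, leaving out prenatal replicate 1, the array that stood apart from its group, gave 11561 calls. Leaving out adult replicate 1, adult replicate 2 or adult replicate 3 gave 5697, 5313 and 5387 calls, testing only probes well above background on all 6 arrays gave 5957, and weighting the arrays by their agreement gave 14744. The weights were 0.172, 1.033 and 3.388 for prenatal replicates 1, 2 and 3, so the weighted prenatal mean rested largely on replicate 3.

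The value table that accompanies the arrays holds 17307 of the tested probes, including all 434 tested probes with lincRNA in their name and none of the 15 messenger RNA probes. Among these tabled probes, 4510 (26.1%) were called, 2153 of them higher in prenatal liver and 2357 higher in adult liver. The share of tabled calls higher in prenatal liver was 47.7%, and 44.9% to 50.7% under the other settings. The majority direction of the tabled calls thus depended on the setting. Of the 15014 other tested probes without a name, 4474 (29.8%) were called, 1711 higher in prenatal liver and 2763 higher in adult liver. As a set against the rest, the tabled probes gave a camera p of 0.0924, and p = 0.241 with an estimated correlation, so the shift between the sets did not pass 0.05. Without adult replicate 1, 2 or 3, the calls were 2883, 2671 and 2713 among tabled and 2811, 2639 and 2671 among the other probes. Array weights gave 7591 and 7148, and 2744 tabled probes were called when only probes well above background on all 6 arrays were tested. The files do not pair the probes with genes. Among the tabled probes well above background on all 6 arrays, ASMM10P000984 rose most, from a log2 signal of -2.36 ± 0.48 (SD, n = 3) before birth to 11.27 ± 0.30 (SD, n = 3) in the adult. It was followed by ASMM10P003383, with -1.03 ± 0.29 (SD, n = 3) and 9.38 ± 0.19 (SD, n = 3). ASMM10P037015 fell most, from 7.18 ± 0.86 (SD, n = 3) before birth to -0.33 ± 0.39 (SD, n = 3), followed by ASMM10P023422, from 7.58 ± 1.55 (SD, n = 3) to 0.06 ± 0.55 (SD, n = 3).

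**Figure D2:**
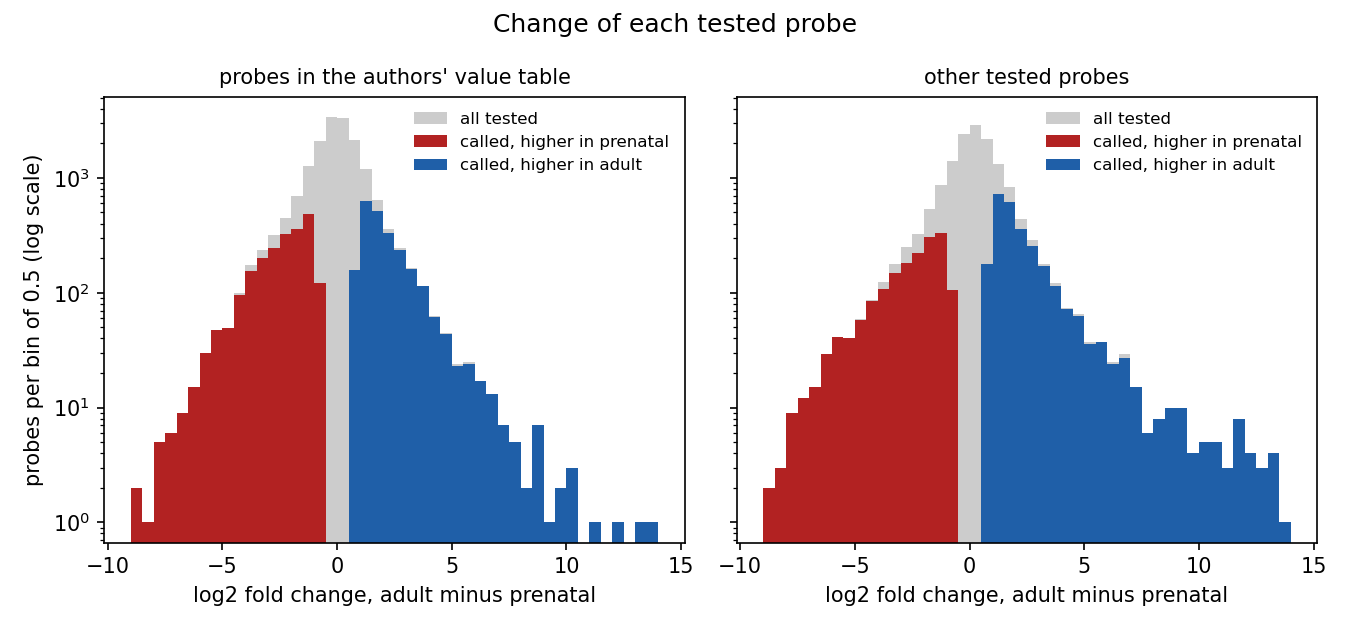
Number of tested probes by log2 fold change, adult minus prenatal, on a log axis, for the 17307 probes of the value table (left) and the other tested probes (right). Grey bars are tested probes within the plotted range and coloured bars those called at an adjusted p under 0.05. Of all tabled calls, 2153 were higher in prenatal and 2357 higher in adult liver. Probes beyond the plotted range are not drawn, among them ASMM10P000478 (15.09, tabled), ASMM10P027182 (14.56) and ASMM10P043618 (-9.22).

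Probe names show 4 smaller families. Among probes named humanlincRNA, 39 of 244 tested were called, 21 higher in adult and 18 higher in prenatal liver. Among probes named mouselincRNA, 42 of 159 were called, 28 higher in adult and 14 higher in prenatal liver. Of 31 tested MM9LINCRNAEXON probes, 8 were called, 6 of them higher in adult liver. Of 240 tested ASMM10UP probes, 56 were called, 39 of them higher in prenatal liver, and the family's camera adjusted p was 0.0512, or adjusted p = 0.962 with an estimated correlation. The camera adjusted p of each of the other 3 families was 0.898.

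Some probes were well above background in one group only. On all 3 prenatal arrays and no adult array, 1335 of 60915 probes were well above background, and on all 3 adult arrays and no prenatal array, 504 were. The number of probes above background per array was 32462 ± 4018 (SD, n = 3) in prenatal and 29662 ± 1945 (SD, n = 3) in adult liver, a difference with an exact two-sided permutation p of 0.4, where the smallest possible is 0.1.

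Pearson correlations across tested probes, which are not independent replicates, ranged from 0.893 to 0.983 among prenatal arrays, from 0.967 to 0.983 among adult arrays, and from 0.709 to 0.845 between the groups. Prenatal replicates 2 and 3 correlated at 0.983, and prenatal replicate 1 correlated with them at 0.893 and 0.915. Arrays that shared a scan date in the scanner output were taken to share a slide, which gave 2 slides. With the slide as a block, 11599 probes were called. Within the slide that held 2 arrays of each group, 9144 probes were called, 7524 of them among the 8987. The log2 difference, adult minus prenatal, within that slide and within the slide that held 1 array of each group was -3.46 and -3.94 for Tfrc, -2.46 and -3.46 for Tuba1b, and 2.65 and 2.95 for B2m.

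**Figure D3:**
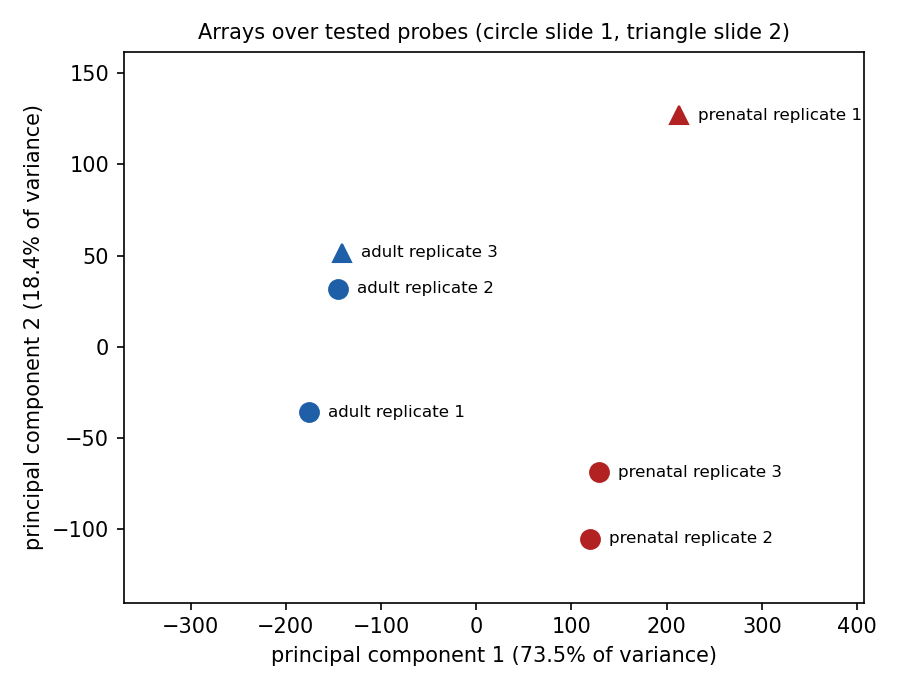
First and second principal components of the 6 arrays over tested probes, holding 73.5% and 18.4% of the variance; circles are slide 1, triangles slide 2, red prenatal and blue adult. The groups part along the first component, and prenatal replicate 1 lies at 127.1 on the second, against -105.6 and -68.9 for the other prenatal arrays.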

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

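The test of a spike-in was chosen after the result was seen. Control spots, which enter no comparison above, carried a signal that differed between the groups. The control probe E1A_r60_a107, printed on 35 spots, was 7.02 higher on the log2 scale in prenatal than in adult liver, with raw medians of 14549, 2827 and 3616 on the prenatal and 14.3, 58.9 and 54.0 on the adult arrays. The control probe E1A_r60_a97 was 2.47 higher. On adult replicate 1, only 17.1% and 2.9% of the spots of these probes were well above background, so that array adds no measured level. Both gave an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. The differences were 6.15 (71.0-fold) and 1.55 (2.93-fold) without adult replicate 1, and 6.09 and 2.16 without prenatal replicate 1. The test took a spike-in RNA added to the prenatal samples to light most of the 10 E1A probes. Only 3 of the 10 E1A probes had most spots well above background on all 3 prenatal arrays. This argues against a spike-in that binds most of the E1A probes, but cannot speak to a spike-in that binds only a few. Binding of a liver RNA to these probes was not tested, and the difference in age stays open.

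On prenatal replicate 1, 8.33% of the spots of negative control probes were well above background, against 0.33% to 2.33% on the other arrays. All 20 spots of 1 such probe were above background there, with a median raw signal of 193.2, and at most 1 spot was on any other array.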

How the results depend on the processing

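The normexp correction, the array weights, the single slide and all counts of tabled and untabled probes were chosen after the data were examined. Direction was kept by every shared call under each setting. The filters, the variance model and the blocks leave the log2 differences as they are or nearly so, and the other settings reuse the same arrays. Kept direction was therefore largely built in. B2m, Tfrc and Tuba1b were called in all 17 settings in which named genes were refitted, with log2 differences of 2.56 to 2.92, -3.76 to -3.46 and -3.00 to -2.46. Of 255 refits of the named genes, 253 kept their side of the threshold; array weights called Hprt at -0.72 and Hsp90ab1 at 0.87. No rescaling moved the median log2 difference of all tested probes by more than 0.1. Some of the counts below moved by over 1.5 times and others by less, and the causes were not tested. Fewer arrays did not always give fewer calls. The fit without prenatal replicate 1 gave 11561 calls, and the fit on only the slide with 2 arrays of each group gave 9144, against 8987 in the main fit.

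Testing only probes above background on all 6 arrays gave 5957 calls (2324 higher in prenatal liver), 5212 at least 2-fold and 2744 tabled. The normexp correction left 4549 calls of at least 2-fold. It added an offset of 50, against raw medians of the processed signal of 11.2 to 24.5 per array. Such an offset shrinks the fold changes of dim probes by construction. How far this accounts for the lower count was not tested. Array weights gave 14744 calls, 6804 higher in prenatal and 7940 in adult liver, with 7591 tabled, 7148 untabled and 5 coding. With the replicate number as a replicate block, 4505 probes were called, all of them at least 2-fold (4505), 1945 higher in prenatal and 2560 in adult liver, 2267 tabled and 2235 untabled. Same-numbered arrays had deviations that correlated at -0.525, -0.349 and -0.313, no array correlated best with its own number, and the block changed no call of a named gene.

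Leaving out each array in turn gave 5313 to 11561 calls, 2256 to 5314 higher in prenatal and 3033 to 6247 in adult liver, 5313 to 10027 of at least 2-fold, 2671 to 5924 tabled and 2639 to 5634 untabled. The lowest counts came without an adult array and the highest without prenatal replicate 1. The mean of the housekeeping list ranged from -0.001 to 0.371, never past the threshold. The authors' values called 4539 tabled probes, 4394 of them shared.

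Leaving out saturated probes was not run because no spot was saturated, the median over probes of a gene because each named gene has 1 probe, and the mean spot signal because only its median was at hand. Signal over background limits what can be read: 20353 of 60915 probes were above background on no array.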

Other observations

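The tests of a wrong label, of the slide, of a dim array and of 5 prime signal loss were chosen after the result was seen, as were the narrower sets of control pairs and the spread of the slope. For 876 loci with lincRNA in the name, the array carries a probe for each strand. Both probes were tested at 53 loci, against 48.2 if detection on the strands were independent (Fisher's exact p = 0.397). The hypothesis that both strands change together was not borne out: across these 53 loci the Spearman correlation of the log2 differences was -0.10, between the outer 2.5% bounds of -0.273 and 0.269 from 100000 random re-pairings (permutation p = 0.477). At 20 loci a single strand was called, and at 0 loci both were. The plus probe was called at 14 loci and the minus probe at 6, too few for this 0 to speak for or against joint change.

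Tested ASMM10P probes with adjacent numbers had log2 differences that correlated at a Spearman rho of 0.106 over 18257 pairs, above the 0.027 that was the highest of 10000 shuffles. The correlation was 0.048 at a distance of 2 numbers and 0.01 at 10. Of 1675 adjacent pairs with both probes called, 65.6% changed in the same direction, against 51% for shuffled calls. Adjacent numbers may mark shared transcripts or neighbourhoods, a hypothesis that the files cannot settle because they give no positions for these probes.

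Prenatal replicate 1 stood apart from the other prenatal arrays, with 4049 tested probes that differed from their mean by more than 4-fold. A wrong group label was argued against by its correlation, higher by 0.154 with the prenatal than with the adult arrays, the separate slide by a difference of 0.0059 for adult replicate 3 of the same slide, and dimness by adult replicates 2 and 3, which were about as dim and correlated with the adult arrays at 0.967 or more. A stronger prenatal profile cannot be told apart. The slope was 0.0822, and 0.0137 when replicates 2 and 3 traded places, both under the bound of 0.1 set beforehand. That exchange moved the slope by more than the distance of 0.0822 from the bound. The first component score of 212.8 exceeded 119.6 and 129.0, but prenatal replicate 1 itself helped to set that component. Nonspecific signal stays open too. The 849 probes above background on this array alone exceeded the 181 to 539 of each other array except prenatal replicate 2, with 2666. These counts cannot decide the question. Probes above background on a single array were not tested, so they enter neither the correlations nor the 4049, and prenatal replicate 2 was the brightest array. Loss of signal at the 5 prime end also stays open: the mean gap between 3 prime and 5 prime control probes exceeded that of replicate 3 by 1.09 (log2) over 6 pairs, against at most 0.93 between adult arrays, by 0.88 against 0.84 over the 3 pairs with most spots above background on every array, and by 0.47 against 0.85 over the 2 mouse pairs. Those adult arrays still correlated at 0.967 to 0.969, which counts against it. However, the outcome depends on which pairs are taken, and in some of the 6 pairs a probe was not well above background. The mean gap over the 6 pairs was 4.6, 3.33 and 3.51 on prenatal replicates 1, 2 and 3. It was 3.76, 4.53 and 4.69 on adult replicates 1, 2 and 3, so prenatal replicate 1 lay within the adult range. Among the prenatal arrays, its gap was the largest in 5 of the 6 pairs. Whether these gaps limit the comparison of prenatal with adult liver was not tested. The biological difference between animals stays open, as untested.

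The 6 arrays can be split into 3 against 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, 8987 probes were called, 8421 of them at least 2-fold, with 4510 tabled and 4474 untabled. The highest other count was 0 in each case. Every other split puts prenatal and adult arrays on both sides, so the difference between the groups enters its residual spread. Low counts there are built in, and they do not show what unchanged probes would give. At an unadjusted p under 0.05 the limma fit gave 13076 probes in the real split and at most 2520 in the others.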
